A study of Mus musculus with 4 samples.

How the data were processed

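RNA was measured in 4 libraries of MC38 cells with an inducible CXCL14 construct. Per the labels' protocols, doxycycline or an equal volume of solvent was added to growing cultures, total RNA was purified on columns from TRIzol lysates, and libraries were made with an Illumina mRNA kit. Groups came from the sample titles, with 2 samples in each. The authors deposited a table of TPM and a table of FPKM, per the file headers, with genes named by symbol. Genome build mm39 is named in the submitters' processing notes. The aligner, the quantifier and the annotation are not given in the sources used here.

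In each library the deposited TPM were a constant times the deposited FPKM, between 3.08 and 3.14, so both tables hold the same estimates under different scaling. The listed genes summed to 97.2% to 97.6% of the fixed total to which TPM scale a library. Low values showed no whole-read steps, so depth could not be recovered, and no counting interval is given. An exact 0 is described as listed at 0. All sample columns were matched to a sample by name.

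Computation was in R 4.3.3 with limma 3.58.1, and in Python 3.11.15 with pandas 2.3.3. Genes with a mean of at least 1 TPM over the 4 libraries were tested on log2(TPM + 1) with limma (lmFit, and eBayes with a mean-variance trend), 2 doxycycline against 2 control libraries with no covariate. Fold changes are on that scale, which understates the change of low genes. Calls are at a Benjamini-Hochberg adjusted p under 0.05. The prior degrees of freedom were 6.98 beside 2 residual degrees of freedom. Ratios are of mean TPM. Of 46 gene lists, 39 had at least 5 tested members and were tested against all other tested genes with camera (two-sided, preset inter-gene correlation 0.01, Benjamini-Hochberg over the 39), with camera using an estimated correlation, and with fry. With the preset correlation, 6 lists passed as higher and 19 as lower. With an estimated correlation 0 passed camera (1 at an unadjusted p under 0.05), with a lowest adjusted p of 0.42. That form rests on the 2 residual degrees of freedom and has little power, so a list's failure to pass it does not argue against a shift. By fry, which asks only whether a list's own genes move, 29 passed in a direction and 38 in either direction. Counts within lists came from the limma test. For 10 lists they differed when adjusted over the list alone.

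The groups, the test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. Named genes are Cxcl14, Cxcr4, Ackr2, Ackr3 and Gpr85, the 10 largest rises and the 10 largest falls past the threshold among genes without a clone-type symbol, and up to 4 passing members of each list with the largest change. Further genes are named as members of a list, after their values were seen: among them Vim, Fn1, Cdh1, Col1a2, Lum, Fap, Fau, Eng, Egfl7 and the macrophage markers. Alternatives were other pseudocounts (0.1 and 0.5), no filter or a mean of at least 5 TPM, FPKM, median-of-ratios scaling, quantile normalization, other variance models, a replicate block, and each replicate left out. With a single replicate left in a group, its library is assumed to vary like those of the other group. Rescaling without mitochondrial-encoded and ribosomal protein genes was added after the data were seen. No paired fit was used as the main one. The sample titles number the cells alike in both groups, but nothing in the labels says that these numbers mark a shared day or stock.

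The test was tried on simulated data with 11359 genes at the real means and spreads, in which 200 were changed. It recovered 22 of 50 genes changed by log2 0.5, 41 of 50 at 1, 48 of 50 at 2 and 50 of 50 at 3, with 5 false among 166 calls. In the data 64.4% of the genes tested were called, so the adjusted threshold was stricter in the simulation. These recovery rates therefore do not carry over to the data. A list shifted by 0.5 was called with the preset correlation, and 0 lists with the estimated correlation. In that run noise was drawn independently for each gene, and no gene outside the list was changed. Near-identical copies were sought with blastn 2.17.0, matching GENCODE M21 transcripts of 154 listed genes to 13607 pseudogene transcripts of that annotation at 97% identity or more over at least 100 bases. GENCODE M21 belongs to an earlier build than mm39, so it was used for sequences and names, and no coordinates are given.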

Results

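The data were gene expression values from RNA sequencing of MC38, a mouse colon carcinoma cell line, that stably carried a CXCL14 construct under a tetracycline-inducible (TetOn) promoter. CXCL14 is a secreted chemokine, and doxycycline is the antibiotic that switches such a promoter on. The 4 libraries fell into 2 groups: 2 control cultures given the solvent PBS, and 2 cultures given 1 µg/mL doxycycline, all harvested after 72 h. The series text calls the 2 samples of each group biological replicates. The tables listed 22186 genes in TPM, a length-scaled share of all transcripts, and FPKM, fragments scaled by transcript length and library size, of which 14330 to 14678 were above 0 in a library. Neither table holds read counts, so the depth of each library is unknown, and levels are given in TPM as mean ± SD of n = 2 libraries per group. No library received doxycycline without the construct, so every difference below is between the doxycycline-treated and control cultures of this line.

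Cxcl14 was the gene the construct was built to induce, and its level checked the labels. Cxcl14 was listed at 27.3 and 29.2 TPM in the controls and 385 and 391 TPM after doxycycline, a rise from 28.2 ± 1.31 to 388 ± 3.97 TPM (SD, n = 2), or 13.8-fold. On the log2(TPM + 1) scale the change was 3.74 with SE 0.06 (limma adjusted p = 1.1e-09). The species of the transgene was not given in the sources used here, so the mouse row may hold endogenous reads, transgene reads or both. Ackr3, an atypical chemokine receptor, fell from 28.3 ± 0.0951 to 5.55 ± 0.706 TPM (log2 fold change -2.16, SE 0.10, limma adjusted p = 2.8e-07). Cxcr4, a chemokine receptor reported to bind CXCL14, was listed at 0 in all 4 libraries. Ackr2 stood at 0.363 and 0.868 TPM in the controls and 0.0517 and 0.0465 TPM after doxycycline, below the level at which genes were tested. Gpr85, a proposed CXCL14 receptor, stood at 6.65 and 6.74 TPM in the controls and 7.62 and 9.27 TPM after doxycycline (log2 fold change 0.29, limma adjusted p = 0.059), and passed the threshold in 5 of 15 alternative settings, with adjusted p from 0.0031 to 0.40. Of the 22 chemokine receptor genes in the table, 19 had a mean below 1 TPM, and of the 3 tested, 0 rose and 1 fell, with 2 rising and 1 falling adjusted over the list alone.

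The comparison between groups asked which genes changed when CXCL14 was induced. Of 11359 genes tested, 3295 were higher and 4017 lower after doxycycline at an adjusted p under 0.05 (limma), together 64.4% of the genes tested. The balance of directions depends on the scaling, with 3649 higher and 3674 lower under median-of-ratios scaling and 3870 higher and 3356 lower under quantile normalization. With a log2 fold change of at least 1 in size, 395 were higher and 882 lower. The largest rises among named genes were of Cdsn, a desmosomal protein of cornified epithelium, from 0.876 ± 0.254 to 64.3 ± 8.16 TPM (log2 fold change 5.12), and Car6, a secreted carbonic anhydrase, from 4.39 ± 0.648 to 169 ± 13.5 TPM (log2 fold change 4.98). The muscle-derived peptide hormone gene Ostn rose from 0.881 ± 0.335 to 56.9 ± 11.7 TPM, the muscle isoform of a cytochrome c oxidase subunit, Cox6a2, from 13.8 ± 4.15 to 327 ± 27.9 TPM, and the stress-induced hormone Fgf21 from 2.28 ± 0.592 to 58.0 ± 0.147 TPM. Adgrg1, P2rx3 and Mamdc2 rose (log2 fold change 4.23, 3.97 and 3.62), and Cxcl14 ranked among the 10 largest rises. Sh2d6, also among them, stood at 0 and 0.282 TPM in the controls and 10.9 and 13.8 TPM after doxycycline. Among the largest falls, Hp, which encodes haptoglobin, stood at 181 and 159 TPM in the controls and 0 and 0.287 TPM after doxycycline (log2 fold change -7.23). Lcn2, which encodes a siderophore-binding protein, fell from 1191 ± 127 to 13.6 ± 1.01 TPM, Cxcl1 from 1597 ± 201 to 34.5 ± 9.15 TPM, and Nos2, the inducible nitric oxide synthase, from 1006 ± 33.4 to 23.8 ± 2.54 TPM. Cxcl5, Saa3, Serpina3n, Cxcl3, Steap4 and Chil1 fell, with log2 fold changes between -4.78 and -6.42. The 20 genes named here passed with limma adjusted p of at most 3.2e-07. The SD of the log2 difference between libraries was 0.18 and 0.16 within groups and 0.69 to 0.74 between them. An exact permutation of 2 against 2 libraries cannot go below p = 0.33 (two-sided), so single genes rest on the spread that limma shares across genes.

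**Figure D1:**
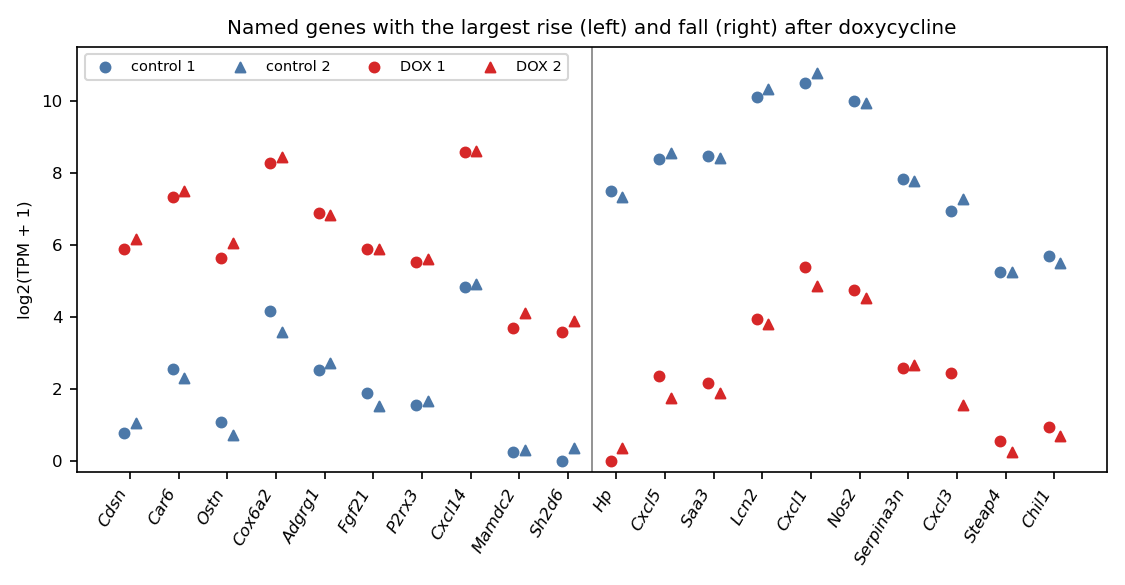
Level of the 10 named genes with the largest rise and the 10 with the largest fall, as log2(TPM + 1), with 1 point per library (blue, control; red, doxycycline). Cxcl14 sits near 28.2 TPM in the controls and 388 TPM after doxycycline, and the points of each group lie apart from those of the other for every gene shown.

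Genes of inflammation fell. Among NF-kappaB and inflammatory target genes, 3 of 31 rose and 24 fell (likewise adjusted over the list alone). Its median log2 change was -1.54 (camera adjusted p = 1.8e-07, and adjusted p = 0.42 with an estimated correlation). Saa3, a serum amyloid, fell from 348 ± 9.87 to 3.09 ± 0.532 TPM, and Cxcl5, a neutrophil-attracting chemokine, from 355 ± 32.2 to 3.23 ± 1.26 TPM. Of the chemokine genes, 0 of 12 rose and 11 fell (likewise adjusted over the list alone). The median of this list was -2.64 (camera adjusted p = 6.2e-06, and adjusted p = 0.42 with an estimated correlation). Cxcl3 fell from 137 ± 22.5 to 3.18 ± 1.77 TPM and Ccl8 from 70.9 ± 5.57 to 5.99 ± 1.22 TPM. Cxcl14 was not a member of that list. Interferon-gamma targets also fell as a list: 3 of 20 rose and 13 fell, and 4 rose and 14 fell adjusted over the list alone. Over its tested members the median was -0.74 (camera adjusted p = 0.0076, and adjusted p = 0.59 with an estimated correlation). The guanylate-binding proteins Gbp5, Gbp6 and Gbp9 fell (log2 fold change -2.73, -2.60 and -1.81), and Socs3, a feedback inhibitor of cytokine signalling, from 58.2 ± 1.90 to 9.49 ± 0.0884 TPM. Type I interferon response genes did not pass as a list: 7 of 42 rose and 15 fell, and 6 rose and 15 fell adjusted over the list alone (median -0.07, with a mean 0.00143 above that of the other genes while camera pointed down, camera adjusted p = 0.55). Isg20 rose from 27.0 ± 1.52 to 75.2 ± 3.38 TPM while Ifitm3 fell from 1648 ± 3.32 to 812 ± 59.8 TPM. MHC class I presentation genes went both ways, as 8 of 23 rose and 8 fell (likewise adjusted over the list alone, camera adjusted p = 0.71), with H2-T23 falling (log2 fold change -1.50) and Tapbpl rising (0.85). Among immune checkpoint genes and ligands of natural killer cells, 1 of 11 rose and 6 fell (likewise adjusted over the list alone). The list lay beside the threshold (camera adjusted p = 0.051), which it passed in 7 of 15 alternative settings, with adjusted p from 0.028 to 0.11. Fas, a death receptor, fell from 36.7 ± 1.43 to 4.57 ± 1.09 TPM, and Pvr and Nectin2, ligands of natural killer and T cell receptors, fell (log2 fold change -0.78 and -0.85). Markers of macrophages in these cultures had a median of 0.0946 TPM in the controls, with Laptm5, C1qa and C1qc listed at 0 in all 4 libraries and Lyz2 at 3.76 and 2.99 TPM in the controls and 2.65 and 3.78 TPM after doxycycline. Cd14 fell from 36.2 ± 0.339 to 6.21 ± 0.272 TPM and Cd68 from 7.64 ± 0.709 to 4.94 ± 0.246 TPM.

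The title of the series names epithelial-mesenchymal transition. Of 38 epithelial junction and keratin genes in the table, 32 had a mean below 1 TPM and 8 were listed at 0 in all libraries, among them Cdh1, which encodes E-cadherin. In the 6 tested, 2 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.43). Cxadr, a junctional adhesion molecule, rose from 6.90 ± 1.94 to 25.5 ± 5.87 TPM, while Elf3, Muc1 and Pkp3 fell (log2 fold change -1.50, -1.31 and -1.02). Mesenchymal and EMT genes fell as a list: 4 of 32 rose and 24 fell (likewise adjusted over the list alone). Across the tested members the median was -0.62 (camera adjusted p = 2.7e-04, and adjusted p = 0.59 with an estimated correlation). Spp1, which encodes osteopontin, fell from 3087 ± 165 to 254 ± 50.4 TPM, and the transcription factor Snai1 from 134 ± 9.72 to 32.5 ± 1.53 TPM. Mmp2 fell (log2 fold change -2.09). Widely used members of the list, chosen after their values were seen, were Vim, which fell from 1569 ± 13.8 to 1037 ± 113 TPM, and Fn1, which fell from 1688 ± 21.0 to 756 ± 46.0 TPM. Targets and components of TGF-beta signalling fell: 0 of 20 rose and 18 fell (likewise adjusted over the list alone). The list's median was -1.13 (camera adjusted p = 2.7e-07, and adjusted p = 0.42 with an estimated correlation). Id3 and Id1, inhibitors of basic helix-loop-helix factors, fell from 609 ± 6.20 to 89.6 ± 5.85 TPM and from 218 ± 3.65 to 34.3 ± 3.03 TPM. Of collagen and basement membrane genes, 2 of 24 rose and 16 fell (likewise adjusted over the list alone). Its median log2 change was -0.67 (camera adjusted p = 0.0053, and adjusted p = 0.59 with an estimated correlation). Dcn, which encodes decorin, fell, with 3075 and 3259 TPM in the controls and 485 and 464 TPM after doxycycline. Col6a1 fell from 384 ± 3.86 to 105 ± 17.3 TPM, whereas Col5a2 rose from 35.8 ± 0.0362 to 171 ± 3.03 TPM. Of matrix proteases and their inhibitors, 4 of 23 rose and 17 fell (likewise adjusted over the list alone, median -0.96, camera adjusted p = 8.9e-04, and adjusted p = 0.51 with an estimated correlation), including Mmp10 from 35.0 ± 1.64 to 5.31 ± 0.00121 TPM and Adamts4 from 10.8 ± 0.367 to 1.80 ± 0.152 TPM. Among fibroblast markers, 0 of 6 rose and 5 fell (likewise adjusted over the list alone, camera adjusted p = 0.0053, and adjusted p = 0.52 with an estimated correlation), led by Pdgfra from 354 ± 5.74 to 30.4 ± 5.16 TPM, with Col1a2, Lum and Fap below 1 TPM in every library.

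ATF4 target genes and ribosome biogenesis genes rose. Among target genes of ATF4, the transcription factor of the integrated stress response, 45 of 47 rose and 2 fell (likewise adjusted over the list alone). The median of this list was 1.34 (camera adjusted p = 9.4e-19, and adjusted p = 0.42 with an estimated correlation). Fgf21 rose from 2.28 ± 0.592 to 58.0 ± 0.147 TPM, Cth, an enzyme of cysteine synthesis, from 13.4 ± 0.299 to 97.7 ± 8.08 TPM, Atf3 from 6.16 ± 1.49 to 45.7 ± 3.46 TPM, and Chac1, a glutathione-degrading enzyme, from 51.4 ± 1.77 to 270 ± 5.47 TPM. The 2 members that fell, named after their values were seen, were Ddit4 (log2 fold change -1.23) and Cebpb (-1.55). The ER unfolded protein response list did not pass: 10 of 30 rose and 13 fell (likewise adjusted over the list alone, median -0.07, while its mean lay 0.22 above that of the other genes, camera adjusted p = 0.60). Its member Hspa5, the main ER chaperone, rose from 937 ± 19.3 to 2991 ± 266 TPM, and Atf6 from 46.0 ± 0.511 to 129 ± 7.74 TPM. Ribosome biogenesis genes and other MYC targets rose almost throughout: 35 of 37 rose and 0 fell, and 36 rose and 0 fell adjusted over the list alone. Over its tested members the median was 0.96 (camera adjusted p = 9.2e-15, and adjusted p = 0.42 with an estimated correlation). Myc itself rose from 157 ± 14.9 to 527 ± 44.2 TPM, Utp20 from 50.0 ± 0.937 to 129 ± 2.86 TPM and Wdr12 from 35.4 ± 0.186 to 90.8 ± 3.45 TPM. Nop56 rose (log2 fold change 1.45) with libraries at 164 and 242 TPM in the controls and 686 and 438 TPM after doxycycline, a call that a robust variance model ended (adjusted p = 0.072, range over alternatives 5.0e-09 to 0.072). The list named for mitochondrial chaperones and proteases rose: 16 of 26 rose and 2 fell (likewise adjusted over the list alone). It also holds factors of mitochondrial DNA upkeep, transcription and translation, among them Tfam, Polg, Polrmt, Tufm and Gfm1, so the counts are not of chaperones and proteases only. Across the tested members the median was 0.38 (camera adjusted p = 2.3e-04, and adjusted p = 0.42 with an estimated correlation). The protease Lonp1 rose from 169 ± 21.2 to 539 ± 15.5 TPM, and the chaperonins Hspe1 and Hspd1 rose (log2 fold change 1.59 and 1.30). Nuclear-encoded respiratory chain genes also rose as a list: 38 of 70 rose and 5 fell (likewise adjusted over the list alone). The list's median was 0.20 (camera adjusted p = 2.3e-04, and adjusted p = 0.42 with an estimated correlation). Uqcrq rose from 77.9 ± 0.265 to 195 ± 7.23 TPM and Atp5g1 from 210 ± 7.57 to 438 ± 7.81 TPM, while Ndufv3 fell from 149 ± 3.65 to 70.7 ± 0.0405 TPM and Uqcrh from 568 ± 1.87 to 283 ± 0.0489 TPM.

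**Figure D2:**
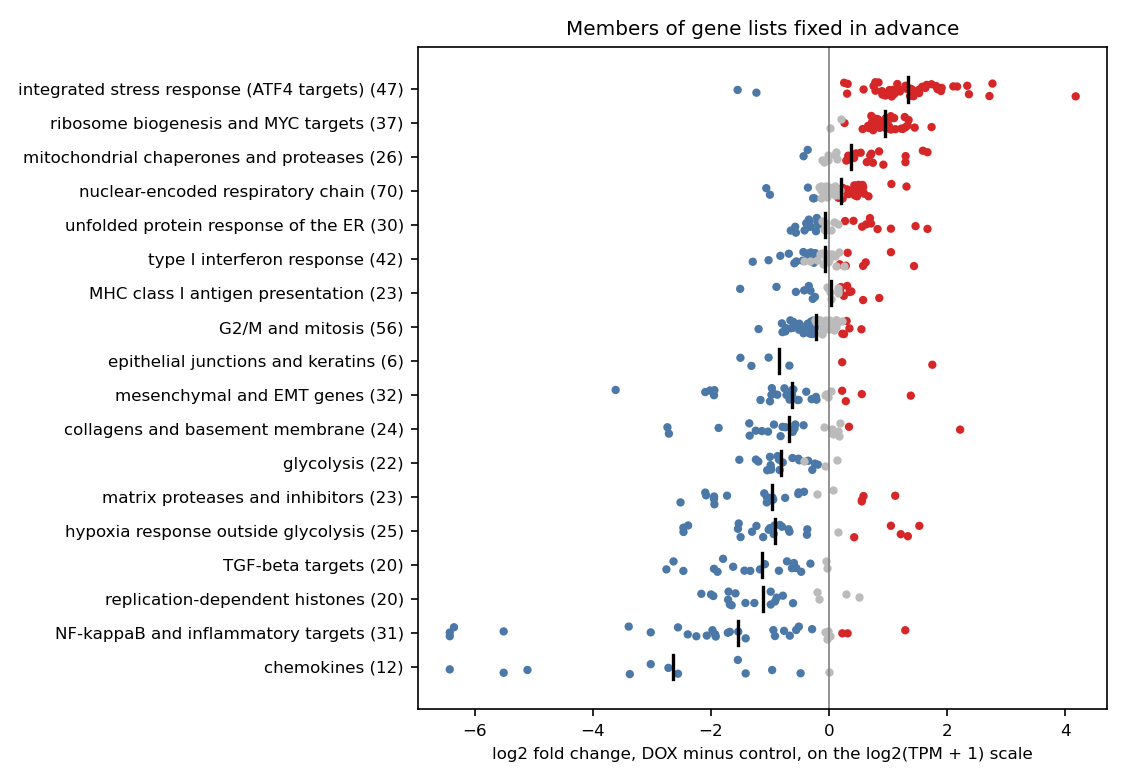
Log2 fold change, doxycycline minus control, of each tested member of 18 gene lists fixed before the data were examined, with the number tested in brackets. Red and blue points passed adjusted p 0.05 and grey points did not, and the black bar is the list's median, from 1.34 for ATF4 targets to -2.64 for chemokines.

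Ribosomal protein genes were listed at low levels in both groups. In the controls and after doxycycline the median was 22.5 and 28.2 TPM for 79 cytosolic, and 2.68 and 3.18 TPM for 78 mitochondrial ribosomal protein genes. It was 175 and 215 TPM for 70 respiratory chain genes, and 553 TPM over the 4 libraries for 28 translation factors outside the ribosome, a group chosen after the values were seen. Fau, a fusion of a ubiquitin-like and a ribosomal protein, stood apart at 1491 and 1422 TPM in the controls and 1609 and 1617 TPM after doxycycline. Of the cytosolic genes, 26 of 79 rose and 1 fell, and 20 rose and 1 fell adjusted over the list alone. Its median log2 change was 0.22 (camera adjusted p = 8.4e-04, and adjusted p = 0.59 with an estimated correlation). The rise leans on control replicate 2: the mean log2(TPM + 1) of the list was 4.63 and 4.39 in the controls and 4.70 and 4.81 after doxycycline, and without that library 17 rose and 6 fell (median 0.10, camera adjusted p = 0.042). Rpl12 rose from 84.6 ± 15.1 to 171 ± 17.3 TPM and Rpl36 from 14.7 ± 0.497 to 30.4 ± 3.32 TPM. Of the mitochondrial genes, 21 of 71 rose and 4 fell, and 14 rose and 3 fell adjusted over the list alone (median 0.15, camera adjusted p = 0.043, and adjusted p = 0.59 with an estimated correlation), with Mrpl32 from 1.88 ± 0.172 to 5.77 ± 0.983 TPM and Mrps6 from 12.5 ± 3.78 to 5.27 ± 0.830 TPM. That list's call was lost in 5 of 15 alternative settings, among them without control replicate 2 (adjusted p = 0.11) and without DOX replicate 2 (0.14), with adjusted p from 3.5e-04 to 0.32. Control replicate 2 held the lowest share of ribosomal protein TPM, 0.354%, against 0.418% in control replicate 1 and 0.440% and 0.469% after doxycycline. All but 8 of 76 cytosolic ribosomal protein genes had a near-identical pseudogene in GENCODE M21, so their single values are uncertain.

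**Figure D3:**
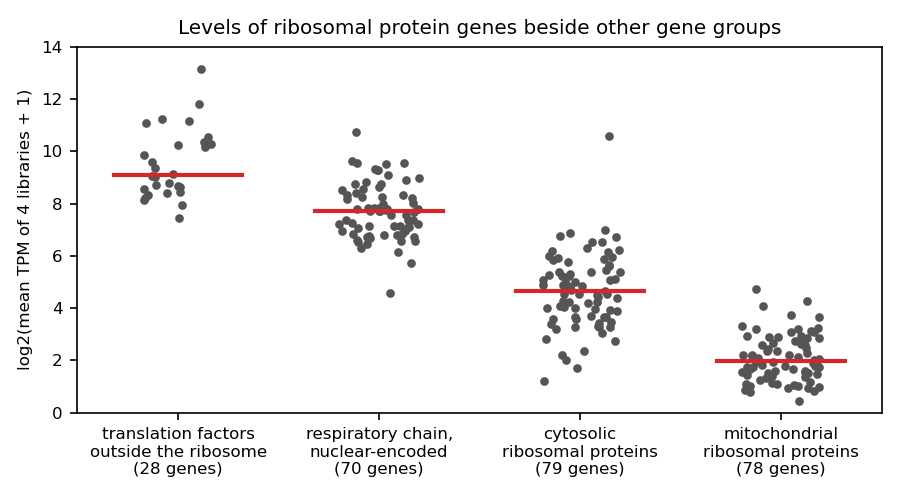
Mean level over the 4 libraries, as log2(TPM + 1), of 28 translation factors, 70 nuclear-encoded respiratory chain genes, 79 cytosolic and 78 mitochondrial ribosomal protein genes, with 1 point per gene and a red bar at each median. The medians run from 553 TPM for translation factors to 2.96 TPM for mitochondrial ribosomal protein genes.

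Glycolytic genes fell: 0 of 22 rose and 19 fell (likewise adjusted over the list alone). The median of this list was -0.81 (camera adjusted p = 1.3e-05, and adjusted p = 0.42 with an estimated correlation). The phosphofructokinase subunits Pfkp and Pfkm fell from 31.8 ± 0.217 to 10.4 ± 0.0598 TPM and from 144 ± 1.94 to 60.6 ± 1.79 TPM, Hk1, a hexokinase, from 100 ± 0.393 to 43.3 ± 4.49 TPM, and the glucose transporter Slc2a1 from 257 ± 3.19 to 124 ± 10.1 TPM. Other hypoxia response genes fell as a list: 5 of 25 rose and 19 fell, and 6 rose and 19 fell adjusted over the list alone (median -0.92, camera adjusted p = 0.0020, and adjusted p = 0.42 with an estimated correlation), including Bnip3, a mitophagy receptor, from 213 ± 3.84 to 37.8 ± 0.887 TPM. Fatty acid oxidation genes fell: 3 of 23 rose and 16 fell (likewise adjusted over the list alone, median -0.36, camera adjusted p = 0.011, and adjusted p = 0.42 with an estimated correlation), with Cpt1a, the carnitine palmitoyltransferase that controls fatty acid entry into mitochondria, at 45.9 and 47.1 TPM in the controls and 11.2 and 10.9 TPM after doxycycline. Immediate early and feedback genes of MAPK signalling mostly fell: 6 of 32 rose and 25 fell (likewise adjusted over the list alone). Over its tested members the median was -0.71 (camera adjusted p = 0.0011, and adjusted p = 0.42 with an estimated correlation). Ier3 fell from 840 ± 31.7 to 99.0 ± 0.450 TPM, the ERK phosphatase Dusp6 from 185 ± 2.81 to 33.8 ± 2.12 TPM, and Phlda1 from 103 ± 3.64 to 16.1 ± 2.75 TPM, while Atf3 rose. Growth factor and angiogenesis genes fell as a list: 6 of 24 rose and 15 fell, and 6 rose and 16 fell adjusted over the list alone. Across the tested members the median was -0.55 (camera adjusted p = 0.027, and adjusted p = 0.42 with an estimated correlation). Hgf, hepatocyte growth factor, fell from 16.8 ± 0.895 to 1.32 ± 0.0435 TPM, Fgf7 from 202 ± 21.7 to 50.6 ± 4.41 TPM and Igfbp5 from 29.8 ± 3.87 to 2.15 ± 0.425 TPM. NRF2 targets of the oxidative stress response fell: 3 of 29 rose and 16 fell (likewise adjusted over the list alone). The list's median was -0.28 (camera adjusted p = 0.025, and adjusted p = 0.42 with an estimated correlation). Fth1, the ferritin heavy chain, stood at 12191 and 12864 TPM in the controls and 4225 and 4225 TPM after doxycycline, and Gstm1, a glutathione transferase, fell from 169 ± 14.3 to 56.9 ± 0.185 TPM.

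Of G2/M and mitosis genes, 5 of 56 rose and 30 fell (likewise adjusted over the list alone). Its median log2 change was -0.22 (camera adjusted p = 0.024, and adjusted p = 0.59 with an estimated correlation). Cdc25b, a phosphatase that activates cyclin-dependent kinases, fell from 69.1 ± 3.20 to 29.7 ± 0.308 TPM, and Aurkb, a mitotic kinase, from 39.9 ± 1.99 to 23.5 ± 0.661 TPM. Without DOX replicate 1 the list's call was lost (adjusted p = 0.20, range over alternatives 0.0097 to 0.20), and without DOX replicate 2 the list had 1 rise and 28 falls. S phase and DNA replication genes did not pass as a list: 10 of 49 rose and 22 fell (likewise adjusted over the list alone, median -0.17, camera adjusted p = 0.15). Dscc1 and Tk1 fell (log2 fold change -1.03 and -0.94), and Mcm2, a subunit of the replicative helicase, rose from 96.8 ± 7.77 to 183 ± 1.11 TPM. Of replication-dependent histone genes, 0 of 20 rose and 16 fell, and 1 rose and 16 fell adjusted over the list alone (median -1.12, camera adjusted p = 0.0012, and adjusted p = 0.42 with an estimated correlation), with H2ac13 from 4.48 ± 0.938 to 0.217 ± 0.0458 TPM. These genes are near-identical to each other, so their single values are uncertain. They also lay near the floor: 25 of 45 in the table had a mean below 1 TPM. The median over all 45 was 1.26 TPM in the controls and 0.476 TPM after doxycycline. Their fall is therefore that of a small residue of reads, and total histone mRNA may differ. Apoptosis regulators fell as a list: 7 of 30 rose and 18 fell (likewise adjusted over the list alone, median -0.37, camera adjusted p = 0.035, and adjusted p = 0.42 with an estimated correlation), with Bmf, which encodes a BH3-only protein, falling from 36.6 ± 0.191 to 7.46 ± 0.0535 TPM. Bcl2l11, another, stood at 17.9 and 18.1 TPM in the controls and 4.23 and 4.61 TPM after doxycycline. That call was lost without control replicate 1 (adjusted p = 0.065, range over alternatives 0.017 to 0.065). p53 targets went both ways: 10 of 30 rose and 13 fell (likewise adjusted over the list alone, median -0.02, or 0.03, 0.08 and 0.01 with median-of-ratios scaling, quantile normalization and FPKM, with a mean 0.14 above that of the other genes, camera adjusted p = 0.61), with Gadd45a rising from 128 ± 1.00 to 588 ± 46.1 TPM and Sesn1 falling from 119 ± 13.6 to 24.6 ± 2.84 TPM.

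Markers of blood and endothelial cells were near 0. In the controls, T and NK cell and neutrophil markers had a median of 0 TPM, B cell markers 0.0295, endothelial markers 0.0807 and erythroid markers 0.0923 TPM. Above 1 TPM, Lck rose from 2.23 ± 0.0647 to 9.60 ± 0.694 TPM and S100a8 fell from 25.8 ± 1.24 to 0.570 ± 0.197 TPM. The 2 endothelial genes tested, Eng and Egfl7, did not pass (limma adjusted p = 0.16 and 0.36), and 0 B cell and 0 erythroid genes reached the level tested.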

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

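The rescaling without mitochondrial-encoded and ribosomal protein genes was chosen after the data were seen, and the other settings before. The Cxcl14 level rose by log2 3.66 to 3.78 across the settings with all replicates, the lowest on FPKM, and by 3.69 to 3.78 with each replicate left out. Genes called higher numbered 2776 to 3077 and lower 3473 to 3656 with each replicate left out, and lists called higher 5 to 6 and lower 18 to 20. Requiring a log2 fold change of at least 1 left 395 higher and 882 lower genes, as that rule is stricter. With an estimated correlation 0 lists were called higher and 0 lower. The planted list of the simulated data was not called either, but its shift was only 0.5. In the data the list mean minus that of other genes was 1.43 for ATF4 targets and -2.66 for chemokines. The simulation therefore does not tell whether shifts of that size would be missed. In the data, with 2 residual degrees of freedom, that form gave an unadjusted camera p of 0.11 for ATF4 targets, although 45 of 47 rose. Its lack of calls therefore does not argue against the shifts. Calls were 45.1% higher in the main fit, 49.8% with median-of-ratios scaling and 53.6% with quantile normalization, which moved the median of all genes by 0.09. Among the 7312 genes called, 3 changed sign under quantile normalization. Lists whose direction turned were never past the threshold, and are given as the list mean minus that of other genes, with camera's direction deciding. They were the type I interferon response without DOX replicate 2 (0.0839), MHC class I antigen presentation with quantile normalization (-0.0308) and without DOX replicate 1 (0.0336), the unfolded protein response of the ER with quantile normalization (0.106), and mitochondrial-encoded transcripts with quantile normalization (-0.0249), with the replicate block (0.0486), without control replicate 1 (-0.260) and without DOX replicate 2 (0.0216). Over the fits with a replicate left out these values ran from -0.0811 to 0.0839 for the type I interferon response, 0.0336 to 0.0849 for MHC class I antigen presentation and -0.260 to 0.357 for mitochondrial-encoded transcripts. The cause was not tested. Of 158 named genes with a test, 7 had a call that differed in at least 1 alternative: Gpr85, ATP6, ATP8, ND5, Mrpl30, Nop56 and Itgb4. Of 39 lists, 8 did in call or direction. Most named genes were picked for a large change that passed, so their count does not describe the calls as a whole. Of all 7312 genes called, 6361 kept their call and direction under quantile normalization and 6476 with no filter on low values. Same-numbered libraries did not deviate together (correlation across genes -0.00526). The sample titles number the cells alike in both groups, without saying whether a number marks a shared day or stock. With only 2 pairs, the correlation cannot settle whether the numbers pair the samples. The replicate block gave 3387 higher and 4114 lower genes. Depth is unknown, so how far it limits low genes cannot be said.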

Other observations

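The acute phase, complement, iron handling and clock groups, the ribosomal protein paralogs and all tests of explanations below were chosen after the values were seen. Acute phase genes fell together: 0 of 16 tested rose and 16 fell (median log2 fold change -4.60), including Lbp, the lipopolysaccharide-binding protein, from 71.2 ± 0.492 to 2.10 ± 0.746 TPM, and the transcription factor Cebpd from 232 ± 5.77 to 9.20 ± 0.806 TPM (SD, n = 2). Of complement genes, 1 of 8 tested rose and 7 fell: C3 fell from 327 ± 25.0 to 12.3 ± 2.12 TPM and C4b from 178 ± 3.28 to 15.9 ± 3.20 TPM, and the member that rose was C1qbp, a mitochondrial protein. Of iron handling genes, 2 of 17 tested rose and 11 fell, with Cp, which encodes ceruloplasmin, from 336 ± 16.0 to 23.3 ± 2.90 TPM, and Slc11a2, an iron importer, from 338 ± 19.2 to 123 ± 4.04 TPM, while Steap1 rose from 42.1 ± 1.31 to 222 ± 1.17 TPM. Of clock genes, 3 of 13 tested rose and 6 fell, with Per3 falling from 20.3 ± 0.0456 to 6.04 ± 0.707 TPM and Ciart rising from 17.7 ± 1.85 to 62.8 ± 1.79 TPM. Hlf fell, with 18.1 and 19.9 TPM in the controls and 1.44 and 1.11 TPM after doxycycline. These groups were picked from the genes that stood out, so their counts are not independent evidence of a direction.

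Lists fixed in advance and not described above were as follows. Of Wnt targets, 2 of 12 rose and 10 fell (likewise adjusted over the list alone, camera adjusted p = 0.013, and adjusted p = 0.42 with an estimated correlation), with Sox9 falling from 96.0 ± 8.23 to 21.4 ± 0.0964 TPM. Of Notch pathway genes, 1 of 8 rose and 6 fell (likewise adjusted over the list alone, camera adjusted p = 0.084), with Hes1 falling from 14.6 ± 0.848 to 3.37 ± 0.0685 TPM. Of YAP targets, 9 of 19 rose and 7 fell (likewise adjusted over the list alone, camera adjusted p = 0.43), with Ankrd1 rising from 35.3 ± 2.26 to 83.2 ± 0.192 TPM and Gadd45b falling from 36.4 ± 0.0355 to 8.32 ± 0.381 TPM. Of autophagy and lysosome genes, 6 of 41 rose and 25 fell (likewise adjusted over the list alone, camera adjusted p = 0.013, and adjusted p = 0.42 with an estimated correlation), with the protease Ctsl falling from 1379 ± 2.01 to 664 ± 7.51 TPM. Of integrin and focal adhesion genes, 6 of 25 rose and 14 fell (likewise adjusted over the list alone, camera adjusted p = 0.42), with the kinase Src rising from 119 ± 5.44 to 312 ± 9.05 TPM. Of heat shock genes, 7 of 17 rose and 5 fell (likewise adjusted over the list alone, camera adjusted p = 0.43), with Hspa1b falling from 19.1 ± 3.11 to 7.96 ± 0.853 TPM. Of cholesterol genes, 8 of 26 rose and 5 fell (likewise adjusted over the list alone, camera adjusted p = 0.43), with Sqle rising from 214 ± 13.1 to 445 ± 2.61 TPM. Of fatty acid synthesis genes, 4 of 21 rose and 8 fell (likewise adjusted over the list alone, camera adjusted p = 0.61), with Dgat2 rising from 59.5 ± 0.873 to 130 ± 16.8 TPM. Its median of -0.08 and the 0.02 by which its mean lay above other genes differed in sign. Mitochondrial-encoded transcripts did not pass as a list: 1 of 13 rose and 2 fell, and 0 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.90). The calls were of ND5, higher, and ATP6 and ATP8, lower, and each was lost in an alternative: ND5 in 3 of 14 settings (adjusted p from 0.0024 to 0.15), and ATP6 and ATP8 with no filter on low values (0.054 and 0.097) and with the robust variance model (0.12 and 0.13). Levels within the list were uneven, with COX1 at 22503 and 23693 TPM in the controls and 20042 and 19678 TPM after doxycycline and COX2 at 130 and 233 TPM in the controls and 141 and 140 TPM after doxycycline. A near-identical pseudogene covered 99.6% of the COX2 and 99.6% of the ATP6 transcript, so their single values are uncertain. ATP6, COX2, COX3, ND3 and ND4L, 99.0% to 99.9% covered, had means of 47.8 to 419 TPM. Genes with 0 copies had higher means, from 545 TPM for ATP8 to 14424 TPM for CYTB. ND4, 63.6% covered, had a mean of 3100 TPM. COX1 was the exception, 100% covered yet with the highest mean, 21479 TPM. Such copies therefore went with low values apart from COX1, and whether they lower them was not tested.

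Of 47 ATF4 target genes 45 rose, and the median log2 fold change of the list was 1.34. Rescaling does not account for it, since at least 45 were called higher under the other TPM scalings run and 44 on FPKM. A general ER stress response and a narrower ATF4 response cannot be told apart, since the ER list's median of -0.0728 covers members that went both ways, 10 of 30 higher and 13 lower and a mean 0.22 above that of the other genes, with Hspa5 (log2 fold change 1.67) and Atf6 (1.47) above the median of the ATF4 targets. Doxycycline inhibits mitochondrial translation, and a response to the drug rather than to CXCL14 may underlie the rise. With 0 libraries given doxycycline without the construct, the drug and the biological explanation, CXCL14, cannot be told apart.

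Of 31 inflammatory genes 24 fell, and the median log2 fold change of the list was -1.54. Macrophages in the control cultures are argued against by a marker median of 0.0946 TPM there, with 11 of 15 markers at a mean below 1 TPM. Laptm5, C1qa and C1qc, the 3 listed at 0 in all libraries, were picked after the values were seen and add nothing to that. Cd14, Cd68 and Lyz2 were above 1 TPM in the controls, and Cd14 and Cd68 fell. Blood and endothelial cells are likewise argued against by low marker medians in the controls. These were 0 TPM for neutrophils and for T and NK cells, 0.0295 for B, 0.0807 for endothelial and 0.0923 for erythroid cells. Of 11 neutrophil markers 7 were listed at 0 in all libraries, although S100a8 fell from 25.8 ± 1.24 to 0.570 ± 0.197 TPM. Fibroblasts stay open: 5 of 6 tested markers fell, Pdgfra from 354 ± 5.74 to 30.4 ± 5.16 TPM. Col1a2, Lum and Fap were below 1 TPM in every library. That fall does not tell fewer fibroblasts from lower levels in the line's own cells. Cell types without a marker list were not tested. Rescaling is argued against by the 23 of 31 genes called lower under the TPM scaling that called fewest, and 21 on FPKM. Bacteria in the cultures, removed by the antibiotic, might also lower such genes, but the tables hold mouse genes only and 0 libraries had doxycycline without the construct, so this cannot be told apart from an effect of CXCL14, which stays open and untested.

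Ribosomal protein genes had low values in both groups, and no biological explanation was tested. Reads lost to near-identical copies are argued against by the 8 genes with 0 such copies among annotated pseudogenes, whose median was 34.0 TPM with a maximum of 117. Short transcripts are argued against by the respiratory chain genes no longer than the median ribosomal protein transcript, at 229 TPM (n = 30). A candidate explanation, as a hypothesis, is that reads of ribosomal protein genes were taken out before quantification. Mitochondrial ribosomal protein genes were also low at 2.96 TPM while translation factors were not, although that group was chosen after the values were seen. The rise of ribosomal protein genes would then be a rise of the reads left. The tested paralogs Rpl7l1, Rpl22l1 and Rps27l had means of 4.92, 7.62 and 1.52 TPM, and Rpl3l, Rpl10l and Rpl39l were listed at 0. What these paralogs would read without such a step is unknown, so they do not bear on the hypothesis. Fau, at 1422 TPM or more, was not low, and no source used here records such a step.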
